A study of Danio rerio with 7 samples.

How the data were processed

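RNA from whole-animal homogenates of 7 adult zebrafish, full siblings of a hybrid cross, was hybridised to Agilent oligonucleotide arrays with 2 colours, 1 array per fish. Per the labels, each fish was labelled with Cy5 and a common reference, also made from whole hybrid animals, with Cy3. No array had its dyes swapped, so a dye effect is part of each ratio and cancels only in differences between fish. The labels give the molecule as total RNA, while their labelling protocol describes heat-denatured DNA of the kind used for genomic hybridisation. How the RNA was labelled is therefore not given in the sources used here.

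Per the file headers, the authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.5.1.1 (protocol GE2_105_Jan09_2, array design 019161). The deposited scanner files give the intensity of each spot in each channel on a linear scale, together with its local background. They also give a processed intensity after the scanner software's own background subtraction and dye normalization. The deposited value table holds log10 ratios, and at all 45220 spots of each array its value equalled the scanner software's own log10 ratio of Cy5 over Cy3. The median of its column was 0 for female 4, 0 for female 7, 0 for female 8, 0 for female 9, 0 for male 5, 0 for male 8 and 0 for male 9. Between 7828 spots (female 7) and 13558 spots (male 5) were set to a log10 ratio of exactly 0, and none of these was well above background in both channels. At every other spot the value was the ratio of the processed intensities, which settles scale and direction. The deposited values were thus not centred beyond the scanner software's dye normalization. Whether the authors centred them in later steps of their own stays unknown.

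The design fixed for the test named the mean signal of each spot, but the deposited files hold the median signal, which was used in its place. Background was corrected by normexp with an offset of 50 on the median signal and the median background, with control spots included in that fit and given no weight afterwards. Each array was normalized within itself by loess, with no scaling between arrays. The 1417 control spots and 98 spots marked as outliers in either channel were then left out, and saturated spots were kept. The 43803 other spots of an array held 43603 distinct probes, 50 of which were printed as 5 repeat spots that were averaged. A probe was tested when its Cy5 signal was well above background on at least 3 of the 7 arrays, which left 22705 probes.

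Probes were named through their RefSeq accession in a gene table of the GRCz12tu assembly, compared without versions. The array was designed on Zv8 (danRer6), so that table served for names and for which genes are neighbours, and no coordinates are given. Of the 43603 probes, 16568 (38.0%) were named, and the others stayed without a gene name here. For results per gene, the tested probe with the highest mean intensity of both channels was taken, which left 8845 genes.

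Fish were grouped by the sex in their labels, 4 females and 3 males. Each fish is a separate animal with no repeat array. Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, female minus male) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The 23 gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over the lists. The lists cover egg coat and oocyte, vitellogenin and oestrogen response, ovary somatic cells, testis somatic cells and androgen synthesis, meiosis, sperm flagellum and motile cilia, germ cell and piRNA, skeletal muscle, liver, intestine and pancreas, brain and nerve, eye, red blood cell, skin, immune cells and interferon response. They also cover the circadian clock, stress and immediate early genes, cell cycle, cytosolic ribosome, oxidative phosphorylation, multicopy immune and chemosensory families and xenobiotic metabolism families. The last 4 were defined by patterns on gene symbols, and the pattern for xenobiotic metabolism also took in steroid enzymes of the cytochrome P450 family such as cyp11a1.1 and cyp19a1b. The pattern for multicopy families took in every symbol that starts with trim, also the muscle ubiquitin ligase gene trim63b. Spread between siblings was the SD of the log2 ratio pooled within sex. It was taken over 10077 probes well above background in Cy5 on all 7 arrays and saturated on none, and a list was set against 10000 random lists of its size matched on mean intensity.

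These groups, tests, lists and the rule for naming genes were chosen before the data were examined. The rule takes, for sex, the 10 genes with the largest positive and the 10 with the largest negative difference among genes that passed, with all 4 females on one side of the males. For spread it takes the 10 genes with the largest SD. In each list it takes the 2 to 4 members with the largest difference among those that passed, or the 2 brightest where none passed. Vtg1, zp2.1, zp3b, amh, cyp19a1a and dmrt1 were always examined as checks of the labels. A gene that this rule names for the sexes is not reported here. Other genes named in the text were chosen after their values were seen. For the comparison of the females with males 8 and 9, the same rule was applied to a fit that was added after the data were seen.

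The file headers place the arrays on 2 slides and in 3 scan sessions. Session 1 held females 7 and 9 and male 9, session 2 held male 8 alone, and session 3 held females 4 and 8 and male 5. Male 8 was on slide 1 and the other 6 arrays are recorded on slide 2, where 3 slide positions occur for 2 arrays each, so the slide records cannot all be right and the scan session was used as the batch. Other background corrections, normalizations, probe filters, variance models, array weights, blocks and thresholds were tried, and each fish was left out in turn. The comparison without male 5, the scan session as a block and the fits within a session were chosen after seeing the data.

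The fits were tested on simulated data of 22674 probes with the real spread without male 5. Noise was independent between probes, there was no session effect, and only a small part of the probes was changed. At 4 females against 3 males, 24%, 80%, 88% and 98% of changed probes were recovered at log2 differences of 1, 2, 3 and 4, and 12 unchanged probes were called. At 4 females against 2 males, the shares were 24%, 58%, 88% and 94%, and 7 unchanged probes were called. The spread with male 5 was larger (median SD 0.49 over all 7 fish, 0.35 without male 5). The shares at 4 against 3 therefore do not hold for the comparison of all 7 fish. Recovery after this adjustment depends on the share of probes changed, so the shares at 4 against 2 are no estimate for the real comparison either. The number of arrays limits the precision, and so does signal over background, which differed between sessions. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.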

Results

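Expression was measured in whole-body RNA from 4 female and 3 male adult zebrafish, full siblings of a hybrid cross, each on 1 array against a common hybrid reference. Per the series design, these siblings served to relate expression to genotype, in particular to copy number variants, so both the difference between the sexes and the spread within a sex bear on it. The genotypes were not analysed here. The share of probes well above background in Cy5 was 33.7% in female 4, 65.3% in female 7, 33.8% in female 8 and 59.6% in female 9. It was 29.8% in male 5, 47.3% in male 8 and 45.9% in male 9. Over repeat spots of one probe, the median SD of the log2 ratio was 0.18 in female 4, 0.07 in female 7, 0.17 in female 8, 0.06 in female 9, 0.22 in male 5, 0.13 in male 8 and 0.09 in male 9. The arrays of scan session 3 (females 4 and 8, male 5) were thus the dimmest and the least precise.

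Genes taken as markers of egg, yolk or testis were examined first, as checks of the sex labels. The egg coat genes zp2.1 and zp3b were close to the reference in the females, at mean log2 ratios of -0.21 ± 0.24 and -0.12 ± 0.73 (SD, n = 4). They were far below it in male 8 (-5.63 and -5.17) and male 9 (-4.14 and -4.82). In the library labelled male 5 they were at -0.09 and 0.61, within the range of the females. The testis genes amh and dmrt1 were at 0.59 and 0.76 in male 8 and at 1.37 and 1.40 in male 9, and averaged 0.05 ± 0.07 and 0.39 ± 0.23 in the females (SD, n = 4), where both were well above background in Cy5 in 2 of the 4. In the library labelled male 5, the dimmest array, neither was well above background (log2 ratios of 0.14 and 0.15), so they weigh little on its label. The yolk precursor genes vtg4 and vtg5 averaged 2.61 ± 0.92 and 2.49 ± 0.43 in the females (SD, n = 4), and were at -1.74 and -1.69 in male 8 and at -2.10 and -1.86 in male 9. In the library labelled male 5 vtg4 was at 2.11, within the range of the females, and vtg5 at 1.11, below the lowest female (1.96). The array had no named probe for vtg1, and neither of the 2 probes for cyp19a1a was tested, since they were well above background in females 7 and 9 only. The egg coat genes thus go against the label of male 5, with vtg4 nearer to the females and vtg5 between the sexes, and each direction drawn from this library below carries that limit.

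**Figure D1:**
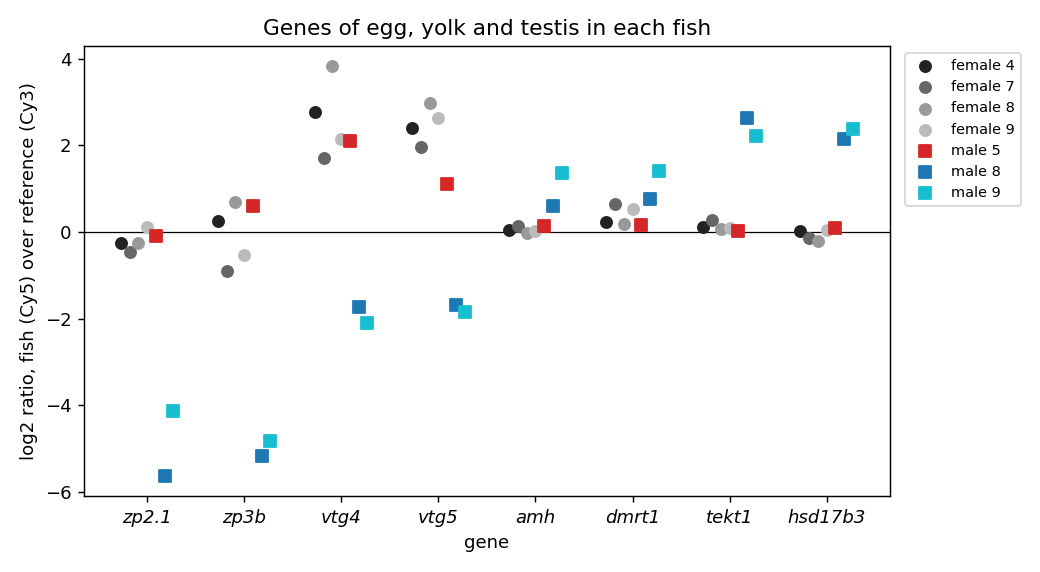
Log2 ratio of fish over reference (vertical axis) for genes of egg, yolk and testis (horizontal axis), with 1 point for each of the 7 fish. For zp2.1 the library labelled male 5 sits at -0.09 beside the females, and males 8 and 9 sit at -5.63 and -4.14.

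The first comparison set the 4 libraries labelled female against the 3 labelled male. Egg coat and oocyte genes had a median log2 difference of 2.12 (female minus male, 30 genes), and cell cycle genes 1.36 (27 genes). Liver genes had a median difference of -0.76 (16 genes) and red blood cell genes of -0.89 (8 genes). No single gene passed: 0 of 22705 probes had an adjusted p under 0.05 by limma, the smallest was 0.539, and 1525 probes had an unadjusted p under 0.05. Per gene, limma called 0 of 8845, with 846 at an unadjusted p under 0.05. With the scan session as a block the count was 0, with 447 at an unadjusted p under 0.05. Within a session, fits have a lone male, assumed to vary like the other fish, so they compare that fish with 2 females and their counts show no difference between the sexes. Limma called 0 in session 3 (females 4 and 8 against the library labelled male 5), with 258 at an unadjusted p under 0.05, and 6684 in session 1 (females 7 and 9 against male 9). Without male 5 the count was 5757.

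Camera with its preset correlation called 16 of the 23 lists over all 7 fish, while 0 passed with an estimated correlation, and fry called 0 for movement in 1 direction (smallest adjusted p = 0.311) and 0 for movement in either (0.329). Egg coat and oocyte (adjusted p = 8.83e-09), cell cycle (3.63e-06) and germ cell and piRNA (median 0.66, 0.023) were higher in females, each with an adjusted p = 0.517 with an estimated correlation. Oxidative phosphorylation (median -0.34, 5.21e-07), sperm flagellum and motile cilia (-0.38, 0.000198), red blood cell (-0.89, 0.00206), liver (-0.76, 0.00289), skin (-0.47, 0.00677), intestine and pancreas (-0.37, 0.00832), muscle (-0.32, 0.00859), brain and nerve (-0.29, 0.00974) and eye (-0.15, 0.00974) were higher in males. So were testis somatic cells (-0.63, 0.0323), xenobiotic metabolism (-0.07, 0.0286), interferon response (-0.29, 0.0459) and stress genes (-0.25, 0.0468). Each of these 13 had an adjusted p of 0.517 with an estimated correlation. The other 7 lists did not pass. Among them, cytosolic ribosome genes had a median of 0.02 and a mean of 0.02 while camera ranked them toward males. Multicopy families had a median of -0.03 and a mean of 0.01. Adjusted over the list alone, 3 members passed in all lists together, against 0 over all probes. The 2 brightest members of each list, 46 genes in all, ran from -1.83 for foxl2l to 3.30 for vtg5, 23 higher in each sex, and none passed. The number of lists was 12 without female 4, 10 without female 8, 8 without male 8, 8 without male 9 and 17 without male 5, and 8 with the scan session as a block.

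The second comparison, added because of the egg coat genes above, set the 4 females against males 8 and 9 and left out the library labelled male 5. Of 30 egg coat and oocyte genes 29 were higher in the females, as were 22 of 27 cell cycle genes and 3 vitellogenin genes. Higher in males 8 and 9 were 7 of 12 testis somatic genes, 6 of 15 sperm flagellum genes, 10 of 25 muscle genes, 5 of 16 liver genes and 5 of 8 red blood cell genes, while 0 of the 23 lists passed camera with an estimated correlation. By limma, 5757 of 22705 probes passed, 2999 higher in females and 2758 higher in males. Of these, 4175 differed at least 2-fold, 2034 and 2141 by direction. Per gene, 2975 of 8845 passed, 1835 higher in females and 1140 higher in males. A probe well above background in males 8 and 9 alone was not tested, so genes seen only in these males are missing from the counts by direction. Of the listed genes on the array, 15 of 25 sperm flagellum genes and 6 of 11 meiosis genes were tested. With the scan session as a block 4595 probes passed (2094 higher in females, 2501 higher in males), and 3437 were shared with the same sign in both fits. Within session 1 (females 7 and 9 against male 9, a lone male assumed to vary like the other fish) 6684 passed, 2873 and 3811 by direction, a count for that 1 fish. The blocked estimate rests on those same 3 fish, because male 8 was the only fish of session 2 and session 3 held no other male. Without male 8, 3432 probes passed, with male 9 as a lone male assumed to vary like the females. With median centring in place of loess, 706 probes passed, 676 higher in females and 30 higher in males, and the median difference of all probes was 0.24 in place of -0.05. It was -0.30 with the scanner software's processed signals and -0.35 with the deposited value table, and changes below are relative to the median of the loess values.

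The largest differences toward females were mostly in egg coat and oocyte genes. Zp3 was higher by a log2 difference of 5.89 ± 0.98 (SE; adjusted p = 0.0115), with a single male value since the spot of male 9 was left out. Its Cy5 spot was saturated on 2 of the 7 arrays, and those of zp3f.1, zpcx, zp2.2, zp2.1, zgc:171977 and si:ch211-12h2.8 on 1 each, so the sizes and order of these differences are approximate. The egg coat genes zp3f.1 (5.57 ± 0.51, adjusted p = 0.00176), zpcx (5.31 ± 0.30, 0.0012, male 9 alone), zp3e (5.22 ± 0.46, 0.00164) and zp2.2 (5.14 ± 0.67, 0.00386) followed, as did kpna7, an oocyte importin (5.14 ± 0.37, 0.00112). Ppt2a.1, a palmitoyl-protein thioesterase, was higher by 5.36 ± 0.59 (adjusted p = 0.00261). Its log2 ratio averaged 5.33 ± 0.99 in females (SD, n = 4) and was -0.07 in male 8, 0.02 in male 9 and 3.84 in the library labelled male 5. Genes with only clone names were si:ch211-12h2.8 (5.78 ± 0.61), zgc:171977 (5.55 ± 0.56) and zgc:56231 (5.11 ± 0.33), with adjusted p = 0.00236, 0.00222 and 0.00108. Of the label checks, zp2.1 (4.67 ± 0.41) and zp3b (4.87 ± 0.45) passed at adjusted p = 0.00159 and 0.00185. Male 5 was left out because of these genes, so their passing restates that choice. With male 5 included, both had an adjusted p = 0.539 by limma. Amh (-0.93 ± 0.23) passed at 0.0294, and dmrt1 (-0.69 ± 0.24) had an adjusted p = 0.0846, or 0.0377 with the scan session as a block. The other tested probe of zpcx and that of zp3b did not pass.

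The largest differences toward males 8 and 9 were spread over several kinds of genes. Gstk4, a glutathione transferase, differed by -5.11 ± 0.14 (SE; adjusted p = 0.000163) and zgc:162239 by -4.75 ± 0.14 (adjusted p = 0.000163), and both were well above background in Cy5 in 2 of the 4 females. The fast muscle troponin gene tnni2b.2 differed by -4.11 ± 0.74 (adjusted p = 0.0103, or 0.0987 with the scan session as a block). Further genes were uck1 (-3.82 ± 0.46), a uridine-cytidine kinase, pimr110 (-3.78 ± 0.23), a Pim-related kinase, apoa2 (-3.76 ± 0.55), an apolipoprotein of the liver, and srfb (-3.65 ± 0.62), a serum response factor. Slc67a1 (-3.64 ± 0.50), a solute carrier, and lpin1a (-3.54 ± 0.64), a phosphatidate phosphatase, differed as well, and uck1 was well above background in Cy5 in 2 of the 4 females. The adjusted p of these genes from uck1 on ran from 0.00104 for pimr110 to 0.0105 for lpin1a. Uck1, srfb and slc67a1 each had 1 other tested probe, which did not pass. The same holds for cyp26b1, syce2, apoa4b.1 and gnat2, which are named below.

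Of the 30 egg coat and oocyte genes, 29 were higher in females, and gtf3aa was at 0.64 with an adjusted p = 0.146. Male 5 was left out for its egg coat values, so this list is no separate check of that choice. Their median difference was 3.13 (camera adjusted p = 2.31e-13, and adjusted p = 0.334 with an estimated correlation), and 29 passed when adjusted over the list alone. The yolk precursor genes vtg4 (4.53 ± 0.56, SE, adjusted p = 0.00341), vtg5 (4.26 ± 0.29, 0.00112) and vtg2 (3.34 ± 0.54, 0.00729) were higher in females. In the same list cyp19a1b, the brain aromatase, was higher in males 8 and 9 (-2.25 ± 0.30, 0.00408), and esr1 did not pass (0.13, 0.53). That list of 5 had a median of 3.34 and did not pass camera (adjusted p = 0.125), with 4 members passing when adjusted over the list alone. Germ cell and piRNA genes had 7 of 12 members higher in females and 0 higher in males, with gtsf1 at 3.17 ± 0.28 (0.00162) and asz1 at 2.13 ± 0.34 (0.00716), both of the piRNA pathway. Their median was 0.99 (camera adjusted p = 0.00837, and adjusted p = 0.345 with an estimated correlation), and 10 members passed when adjusted over the list alone, 9 higher in females and 1, the Piwi gene piwil1, higher in males 8 and 9. Piwil1 was at -0.88 (0.0535 over all probes), or 0.16 with median centring, and its other 2 probes were at -0.74 (0.0179) and 0.10 (0.773). Over all probes, 6 members were higher in females and piwil1 alone higher in males 8 and 9 with the scan session as a block. With probes well above background on all 7 arrays the camera adjusted p of the list was 0.0996.

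Of 12 genes of testis somatic cells and androgen synthesis, 7 were higher in males 8 and 9. They included hsd17b3, which makes testosterone (-2.33 ± 0.16, SE, adjusted p = 0.00112), inha, an inhibin subunit (-1.52 ± 0.26, 0.00905), cyp26b1, which degrades retinoic acid (-2.37 ± 0.42, 0.0096), and hsd11b2, which oxidises glucocorticoids (-2.48 ± 0.60, 0.0278). With the scan session as a block, cyp26b1 and hsd11b2 had an adjusted p = 0.0751 and 0.226. Cyp11a1.1 (1.51, 0.0311) and hsd3b2 (1.36, 0.039), enzymes of steroid synthesis, were higher in females. The list's median was -1.06 (camera adjusted p = 0.00541, adjusted p = 0.345 with an estimated correlation, and 0.111 with probes well above background on all 7 arrays), and 10 members passed when adjusted over the list alone. Of 4 genes listed as ovary somatic, only foxl2l passed, and it was higher in males 8 and 9 (-2.90 ± 0.29, 0.0021), while fstb was at -0.95 (0.0716). Foxl2l is known as a germ cell gene of oogenesis, so it is no marker of ovarian somatic cells. Foxl2l and inha were well above background in Cy5 in 2 of the 4 females. That list had a median of -0.48 and a camera adjusted p = 0.119, or 0.0404 with median centring, with 2 members passing when adjusted over the list alone. Of 6 meiosis genes, sycp1 (-2.80 ± 0.59, 0.0172) and syce2 (-1.02 ± 0.29, 0.0449), which build the synaptonemal complex, were higher in males 8 and 9. Ccna1, a germ cell cyclin, was higher in females (1.77 ± 0.37, 0.017, or 0.0706 with the scan session as a block). The meiosis list had a median of -0.05, a camera adjusted p = 0.547 and 3 members passing when adjusted over the list alone. With no filter on dim probes its median was -0.18 and its camera adjusted p 0.0259, and with processed signals its median was 0.36 (0.795).

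Sperm flagellum and motile cilia genes had 6 of 15 members higher in males 8 and 9 and 0 higher in females. Cimap1b (-2.43 ± 0.24, SE, adjusted p = 0.0021), tekt1 (-2.28 ± 0.17, 0.00126), tekt2 (-1.98 ± 0.34, 0.00929) and ropn1l (-1.90 ± 0.25, 0.00407), parts of the sperm tail or cilium, differed most. Tekt1 was well above background in Cy5 in 2 of the 4 females and ropn1l in 1. The list's median was -0.55 (camera adjusted p = 0.000236, and adjusted p = 0.305 with an estimated correlation), with 6 members passing when adjusted over the list alone. With probes well above background on all 7 arrays the median was -0.06 and the camera adjusted p 0.772. That filter removes genes that are dim in any fish, cimap1b, tekt1, tekt2 and ropn1l among them, so it cannot decide on genes seen mainly in males.

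In the lists of muscle, liver, and intestine and pancreas genes, the members that passed were a minority, and all of them were higher in males 8 and 9. The RNA came from whole animals, so the share of a tissue and expression within it cannot be told apart. That limit holds for the other tissue lists as well. Of 25 muscle genes 10 passed, among them the calcium pump atp2a1 (-3.34 ± 0.54, SE, adjusted p = 0.00768), the slow myosin smyhc2 (-3.11 ± 0.23, 0.0012) and the calsequestrin casq1b (-2.74 ± 0.58, 0.0181, or 0.1 with the scan session as a block). Of 16 liver genes 5 passed, among them apoa2 and apobb.1 (-2.20 ± 0.41, 0.0117), both apolipoproteins, and the complement factor cfb (-2.10 ± 0.60, 0.0449, or 0.144 with the block). Of 18 intestine and pancreas genes 6 passed, with the chitinase chia.2 at -2.53 ± 0.61 (0.0276, or 0.215 with the block) and the apolipoprotein apoa4b.1 at -2.24 ± 0.58 (0.0334, or 0.232 with the block). The medians were -1.63 for muscle (camera adjusted p = 9.29e-06), -1.59 for liver (0.000121) and -1.38 for intestine and pancreas (0.000119), each at an adjusted p = 0.345 with an estimated correlation. Adjusted over the list alone, 11, 6 and 7 members passed. With the scan session as a block, 5 muscle, 3 liver and 0 intestine and pancreas genes passed. Then the liver median was -0.70 (camera adjusted p = 0.0166) and that of intestine and pancreas -0.51 (0.123).

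In the brain and nerve list 5 of 13 genes were higher in males 8 and 9, with the myelin gene mpz at -2.87 ± 0.38 (SE, adjusted p = 0.00417) and the synaptic gene snap25a at -2.64 ± 0.44 (0.00839). In the eye list 5 of 19 were, with the cone genes gnat2 at -2.39 ± 0.48 (0.0149) and pde6c at -1.95 ± 0.36 (0.0117, or 0.0767 with the scan session as a block). In the red blood cell list 5 of 8 were, with the globins hbba2 at -3.02 ± 0.82 (0.0395) and hbaa2 at -2.91 ± 0.77 (0.0361). In the skin list 5 of 11 were, with the keratin krt8 at -2.79 ± 0.51 (0.0114) and icn at -2.26 ± 0.34 (0.00612). The medians were -0.66 for brain and nerve (camera adjusted p = 0.00306), -0.30 for eye (0.00202), -1.54 for red blood cell (0.000712) and -0.78 for skin (0.000612). With an estimated correlation the adjusted p was 0.334 for red blood cell and 0.345 for the other 3. Adjusted over the list alone, 5, 5, 6 and 6 members passed.

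Of 11 immune cell genes, b2m (-2.08 ± 0.38, SE, adjusted p = 0.0113, or 0.0521 with the scan session as a block) and cxcr4b (-1.65 ± 0.26, 0.00656) were higher in males 8 and 9. Of 8 interferon response genes, stat1a (-1.29 ± 0.33, 0.0314, or 0.158 with the block) and trim25 (-0.58 ± 0.16, 0.0395), well above background in Cy5 in 2 of the 4 females, were. Their medians were -0.66 (camera adjusted p = 0.0102) and -0.42 (0.041), both at an adjusted p = 0.345 with an estimated correlation, and 2 and 4 members passed when adjusted over the list alone. With the block 1 immune cell gene and 1 interferon gene passed, and the immune cell median was -0.30 (camera adjusted p = 0.0327). With scaling between arrays the camera adjusted p was 0.0603 for immune cells and 0.0754 for interferon response. The interferon list had a camera adjusted p = 0.0898 with the block, 0.0526 without female 9, 0.0582 without male 8 and 0.0701 without male 9. Of 18 circadian clock genes, per1a (-3.23 ± 0.60, 0.0116, or 0.0703 with the block), tefa (-1.96 ± 0.23, 0.00284) and bhlhe40 (-1.40 ± 0.37, 0.036) were higher in males 8 and 9, and cry5 was higher in females (0.97 ± 0.28, 0.0488, or 0.329 with the block). That list had a median of -0.20 and a camera adjusted p = 0.0868, with 3 members passing when adjusted over the list alone.

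Of 23 stress and immediate early genes, 6 were higher in males 8 and 9. They included the glucocorticoid-responsive fkbp5 (-2.62 ± 0.58, SE, adjusted p = 0.0203, or 0.17 with the scan session as a block), the cytokine suppressor socs3a (-2.66 ± 0.59, 0.0214, or 0.162 with the block) and the chaperone hsp90aa1.2 (-2.49 ± 0.22, 0.00166). The chaperone genes hspa5 (2.14 ± 0.27, 0.00366) and dnajb1b (1.62, 0.00423) were higher in females. The median of the list was -0.78 (camera adjusted p = 0.0101, and adjusted p = 0.345 with an estimated correlation), and 8 members passed when adjusted over the list alone. With the block 5 members were higher in females and 1 in males, and the median was -0.03 with a camera adjusted p = 0.647. It was -0.37 with 0.263 without male 8, and the camera adjusted p was 0.0603 with scaling between arrays and 0.0691 with probes well above background on all 7 arrays.

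Cell cycle genes were higher in females at 22 of 27 members, with the mitotic cyclins ccnb2 at 4.33 ± 0.37 (SE, adjusted p = 0.00155) and ccnb1 at 4.17 ± 0.33 (0.00143). The replication genes mcm6 (-1.90, 0.0129) and mcm3 (-0.83, 0.0153) went the other way. The list's median was 2.09 (camera adjusted p = 4.42e-08, and adjusted p = 0.334 with an estimated correlation), with 26 members passing when adjusted over the list alone. Oxidative phosphorylation genes had 27 of 63 members higher in males 8 and 9, led by the muscle isoforms cox7a1 (-2.53 ± 0.54, 0.0181) and cox6a2 (-2.34 ± 0.52, 0.0211), which had an adjusted p = 0.147 and 0.158 with the scan session as a block. With that block 4 members were higher in males and 2 in females, 0 passed when adjusted over the list alone, and the adjusted p of fry was 0.174 in place of 0.0182. The 3 members higher in females were cox5ba (1.40, 0.0469), cox7a2a (1.31, 0.0269) and cox6a1 (0.99, 0.00738). The median was -0.62 (camera adjusted p = 1.61e-07, and adjusted p = 0.345 with an estimated correlation), turning to 0.50 with median centring, where the median of all probes was 0.24 (camera adjusted p = 0.163), and 35 members passed when adjusted over the list alone. Of 71 cytosolic ribosome genes, rpl7l1 was higher in females (2.24 ± 0.26, 0.00276) and rps8b in males 8 and 9 (-2.15 ± 0.37, 0.00878). That list had a median of -0.10 and a camera adjusted p = 0.171, with 2 members passing when adjusted over the list alone. It passed with Cy5 alone (-0.18, 0.0149) and with the mean of all probes of a gene (-0.17, 0.0443), while its median was 0.39 with processed signals (0.482) and 0.18 with scaling between arrays (0.2).

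Of 50 genes of multicopy immune and chemosensory families, 5 were higher in each sex, with trim101 at -2.46 ± 0.50 (SE, adjusted p = 0.0154, or 0.0663 with the scan session as a block) and trim35-29 at 2.18 ± 0.36 (0.00799). The list had a median of -0.16 and a camera adjusted p = 0.148, with 10 members passing when adjusted over the list alone. It passed with processed signals (median -1.04, camera adjusted p = 0.0271), the deposited value table (-1.07, 0.0270), Cy5 alone (-0.22, 0.0490) and median centring (-0.06, 0.00136). With probes well above background on all 7 arrays its median turned to 0.63 (0.928). Of 56 genes of xenobiotic metabolism families, 11 were higher in males 8 and 9 and 4 in females, with gstk4 and gstk1 (-2.83 ± 0.38, 0.00431) differing most. The median was -0.21 (camera adjusted p = 0.00404, and adjusted p = 0.345 with an estimated correlation), turning to 0.02 with median centring, where the median of all probes was 0.24, and 15 members passed when adjusted over the list alone. With the block the median was -0.01 and the camera adjusted p 0.0873. The lists of meiosis, cytosolic ribosome and circadian clock genes, which did not pass, had medians of 0.60, 0.71 and 0.10 with median centring. Over the 23 lists, camera called 17 and fry 15 for movement in 1 direction, and fry called 23 for movement in either, while camera with an estimated correlation called 0. With the scan session as a block these counts were 13, 10, 16 and 0.

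**Figure D2:**
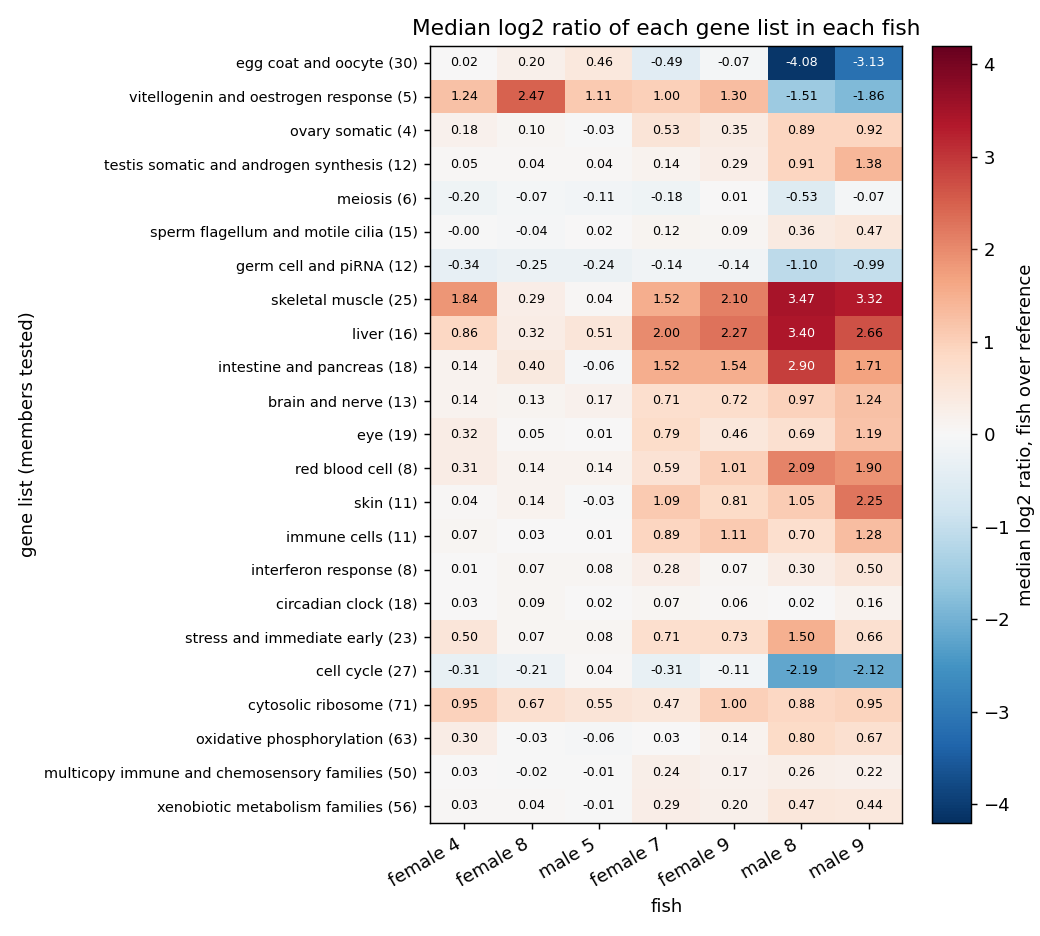
Median log2 ratio of fish over reference for each of the 23 gene lists (vertical axis, members tested in brackets) in each of the 7 fish (horizontal axis), with the colour and the printed number giving the median. Egg coat and oocyte genes are at -4.08 in male 8 and -3.13 in male 9, at 0.46 in the library labelled male 5 and between -0.49 and 0.20 in the females.

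The spread between siblings of a sex was examined because the study drew on differences between siblings. Among lists with at least 5 members, muscle genes had the largest median SD, followed by intestine and pancreas, egg coat and liver genes. The library labelled male 5 lay far above males 8 and 9 for egg coat genes and far below them for muscle genes. The largest pooled SD of the log2 ratio were those of the troponin tnni2a.3 (2.70), the egg coat gene zp3.1 (2.55), the troponin tnni2b.2 (2.49), the myosin light chain mylpfa (2.31) and si:ch211-12h2.8 (2.26). They were followed by zp2.3 (2.17), zp3b (2.12), zp3e (2.09), the myosin light chain myl10 (2.08) and the parvalbumin pvalb2 (2.06). Without male 5 the SD of these genes was 2.27 for tnni2a.3, 1.76 for mylpfa, 1.42 for pvalb2, 1.32 for si:ch211-12h2.8, 1.07 for tnni2b.2 and 1.02 for myl10. That of the egg coat genes fell to 0.31 for zp3.1, 0.49 for zp2.3, 0.64 for zp3b and 0.65 for zp3e. Over 10077 probes the median SD was 0.49, and 4960 probes (49.2%) had an SD of at least 0.5 and 1463 (14.5%) of at least 1. Without male 5 the median was 0.35 and the counts 2736 and 401. Over the 4 females alone the median was 0.33 with 2543 probes at 0.5 or more, and over the 4 females within their scan sessions it was 0.22 with 1346 (13.4%). With the Cy5 channel alone, without the reference, the 4 females had a median of 0.27 with 1548 such probes, and within sessions 0.20 with 944. With single arrays per fish, differences between fish have no replicate check.

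Muscle genes had a median SD of 1.67 over the 7 fish, 0.98 over the 4 females and 0.99 over the females within sessions, each above all 10000 random lists (percentile 100). Liver genes were at 1.29, 0.99 and 0.53 (percentile 100 each), and intestine and pancreas genes at 1.39, 0.95 and 0.51 (100, 100 and 99.98). The random lists hold unrelated genes, while members of a tissue list can move together in 1 fish, so a percentile is no test over fish. Within sessions in the females, the median SD of stress genes was at percentile 97.96, multicopy families at 99.35, xenobiotic metabolism at 96.26, brain and nerve at 94.73, immune cells at 92.89, cytosolic ribosome at 92.85, skin at 91.18 and oxidative phosphorylation at 86.65. Testis somatic cells were at 82.43, egg coat and oocyte at 82.06, circadian clock at 80.68, cell cycle at 71.47 and germ cell and piRNA at 13.1. The multicopy list had 14 members here, among them the muscle gene trim63b, so its percentile is not that of immune and chemosensory genes alone. Over all 7 fish, egg coat and oocyte genes were at percentile 99.99 and cytosolic ribosome genes at 0, the latter with a median SD of 0.40. The other 7 lists had under 5 members among these probes and were given no percentile.

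Against the reference, males 8 and 9 differed most, and the library labelled male 5 least with loess but not with every normalization. At least 2-fold differences were found at 7794 probes in male 8 (3581 higher, 4213 lower) and at 6866 in male 9 (4357 higher, 2509 lower). In the library labelled male 5 they were found at 1548 (854 higher, 694 lower). The females had 2377 (female 4), 2242 (female 7), 2272 (female 8) and 2191 (female 9). Higher outnumbered lower in each female, by 1458 to 919 in female 4, 1903 to 339 in female 7, 1361 to 911 in female 8 and 1850 to 341 in female 9. The reference is no group of fish, so these counts have no test. With median centring the counts were 5073 in female 4, 3594 in female 7, 5304 in female 8, 2277 in female 9, 4234 in male 5, 8895 in male 8 and 10571 in male 9, so that females 7 and 9 lay below male 5. They did too with processed signals (6229 and 5850 against 7542) and with the deposited value table (5856 and 5823 against 7307).

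Across probes, the log2 ratios of males 8 and 9 had a Pearson correlation of 0.87, although these fish were scanned in different sessions. The library labelled male 5 correlated at 0.38 with male 8 and 0.30 with male 9, and at 0.78 and 0.85 with females 4 and 8, which were scanned with it. With females 7 and 9 of the other session it correlated at 0.44 and 0.47. Female pairs of one session correlated at 0.70 and 0.84, and female pairs of different sessions at a median of 0.56. The Cy3 reference itself had a median correlation of 0.994 within sessions and 0.762 between sessions, over 2747 probes bright in Cy3 on all arrays. These correlations are across probes, which are not independent replicates.

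**Figure D3:**
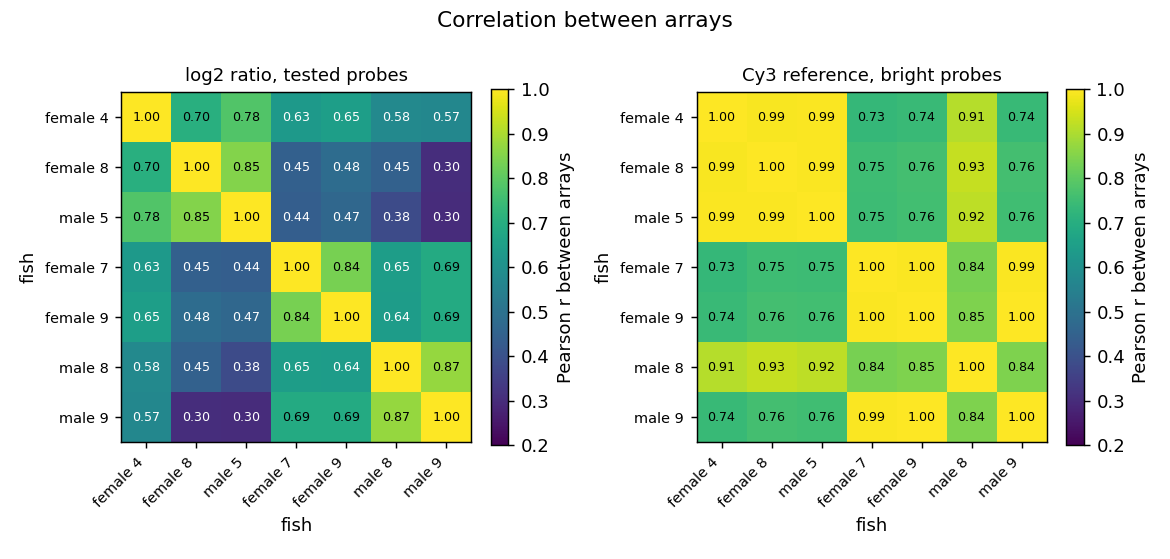
Pearson correlation between each pair of the 7 arrays (both axes, fish; colour and printed number, r), on the left for the log2 ratios of tested probes and on the right for the Cy3 reference at bright probes. Males 8 and 9 correlate at 0.87 on the left, male 5 with female 8 at 0.85, and on the right pairs scanned together are at 0.99 or above.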

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

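The tests of a swap and of a single wrong label for male 5 were chosen only after the result was seen. The tests of a mixture in male 5 and of other probes for a female apart from her sisters were chosen before theirs. Of 121 groups of 4 values examined for a single fish far from the rest (Dixon's ratio of gap to range above its critical value at the 95% level), 4 stood out, and chance alone gives about 1 in 20. The slow myosin smyhc2 was at a log2 ratio of 0.62 in female 7 and between 0.00 and 0.08 in the other females (ratio 0.878). Fkbp5 was at 1.88 in female 8 and between 3.54 and 3.72 in the others (ratio 0.906). Gstk1 was at 0.19 in female 8 and between 1.30 and 1.52 in the others (ratio 0.84). Zp3.1 was at -0.62 in female 7 and between -0.25 and -0.18 in the others (ratio 0.848).

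The library labelled male 5 lay with the females at genes that set the females apart from males 8 and 9. A swap with a fish labelled female needs a partner, and 0 libraries labelled female had egg coat genes at the level of males 8 and 9. A mixture with male RNA making up a share of 0.1 or more needs male 5 at least that share of the way from females 4 and 8 to males 8 and 9 on the linear scale, and its median position over 776 probes higher in those males was -0.0409 (interquartile range 0.0663). What stays open is a single wrong sex label, or an exchange with a fish outside these 7, since the median log2 position of male 5 was -0.0258 over 514 probes higher in females and -0.13 over those higher in males, where a male would lie near 1. A fish recorded as male whose own gonad gives these values stays open too and was not tested.

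At 74 of 10074 probes, 1 female lay at least 2 log2 units from her sisters while these stayed within 1, and female 8 was the one apart most often (24 probes higher, 23 lower). If the cause lay at the probe alone, as with a sequence variant under it, other probes of the gene would show little of the shift, and their median share was 0.3156 with an interquartile range of 0.80 over 26 comparisons. That value lies between the bounds of 0.25 and 0.5 set beforehand and does not decide, with 10 shares over 0.5 and 13 under 0.25. Tpma, fabp6 and txnipa entered from both of their probes, each time with a share over 0.5. The comparisons are thus not independent. With each gene entered once the median would fall under 0.25, the bound set beforehand for a cause at the probe alone. The outcome thus depends on how genes are counted, and the test does not decide. Pvalb4 (-2.36 and -2.26), tpma (-2.56 and -2.35) and txnipa (-2.10 and -2.01) in female 8 and fabp6 (2.56 and 2.32) in female 7 moved in both of their probes, while for kif4 (3.04, against 0.74 at its other probes) and lmnb1 (2.59 against 0.26) they did not. For the first kind a difference between these fish may be the source, for the second a cause at the probe may be, and no biological explanation was tested.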

How the results depend on the processing

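The comparison without male 5, the scan session as a block and their combinations were tests chosen only after the result was seen. Over all 7 fish, 0 probes passed under each alternative except array weights (4026, male 5 at weight 0.18), the fish number as a block (4083) and leaving out male 5. Leaving out each fish in turn gave 0 to 5757, the highest without male 5. The fish numbers are shared by 2 pairs (8 and 9), whose deviations correlated at -0.13 and 0.43, so they were not taken to pair the fish. That block also gives male 5 a number of its own and so removes it from the contrast. The lists passing camera fell from 16 to 9 with scaling between arrays, 8 with the slide as a block and 8 with the scan session as a block. Leaving out each fish gave 8 (males 8 or 9) to 17, with 10 without female 8.

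Without male 5, the 5757 probes became 9158 with processed signals, 9506 with the deposited value table, 11236 with Cy5 alone, 706 with median centring (7453 with that centring and the scan session as a block, 7395 of them higher in females), 1978 with scaling between arrays and 272 with that scaling and the scan session as a block. They were 3438 with the slide as a block, which sets aside male 8, alone on its slide. At an adjusted p under 0.01 they were 2259, and per gene 2975, both fewer by construction. Leaving out a fish gave 3432 (male 8, which leaves a lone male assumed to vary like the females) to 4804 probes and 15 to 17 lists. Over the alternatives without male 5, 13 to 19 lists passed. With median centring the medians of oxidative phosphorylation (0.4965) and xenobiotic metabolism (0.0211) changed sign, but that setting also moved the median of all probes from -0.05 to 0.24. The latter list stays below that median (camera adjusted p = 0.000151), and the former lies above it (0.163). The probes with an SD of at least 0.5 rose from 4960 to 8161 with processed signals, 8109 with the value table and 8700 with median centring, and leaving out each fish gave 2736 (male 5) to 5301. The median count at least 2-fold from the reference rose from 2272 to 9058, 8871 and 5073 under the same settings and to 4161 with an offset of 10, and fell to 374 at 4-fold. Where no construction is named, the cause was not tested.

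Of 89 genes named in the comparison without male 5, 22 kept their direction and their side of the threshold under every alternative, as did 9 of 23 lists. Median centring ended 60 of those calls, scaling between arrays 40, the slide block 31 and the scan session block 20, and leaving out male 8 ended 31. Aquantile changes only the brightness, not the ratio, so it moves no ratio. The filter on all 7 arrays is already part of the spread and so leaves the spread as it was. It did end the camera calls of the testis somatic, sperm flagellum, germ cell and stress lists without male 5. Dim Cy5 signal in session 3 limits females 4 and 8 and male 5 most.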

Other observations

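The tests of the dimmer session and of splits of the fish for probes were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Of the lists with at least 5 members, muscle genes differed most between sisters scanned together (median SD 0.99), followed by liver (0.53) and intestine and pancreas genes (0.51). The median log2 ratio of 25 muscle genes was 1.84 in female 4, 1.52 in female 7 and still higher in female 9, but 0.30 in female 8, and it was 3.47 and 3.32 in males 8 and 9 and 0.04 in the library labelled male 5, scanned with females 4 and 8. Pklr, a pyruvate kinase, was at 2.84 in female 4 and -0.59 in female 8, and the muscle ubiquitin ligase gene trim63b at 2.27 and 0.33. Txnipa, a gene responsive to glucose, was at 2.19 in female 4 and 0.13 in female 8. The glucocorticoid-responsive fkbp5 was lowest of the females in female 8 as well, at 1.88. Liver genes had medians of 0.86 in female 4, 0.32 in female 8 and 2.27 in female 9, with female 7 closer to female 9 than to the others, so that they follow the scan sessions. Fabp6, a bile acid carrier of the intestine, was at 4.04 in female 7 and between 1.23 and 1.64 in the other females by 1 probe.

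The library labelled male 5 differed from every other fish in a few genes. Zp3.1 was at 4.46 in it and between -2.85 and -0.18 in the other 6 fish. Several muscle genes were lower in it than in any other fish, tnni2a.3 at -3.14 against -1.80 or more, pvalb2 at -2.56 against -1.29 or more and tnnc2.2 at -0.34 against 0.82 or more. Acyltransferase gene mboat7 was at 2.03 against 0.72 or less.

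The Cy3 reference, which the labels describe alike for all arrays, did not give the same values in all sessions. If session 3 were only dimmer, bright unsaturated probes would correlate between sessions as they do within them (0.994), and they correlated at a median of 0.7621, which argues against dimness alone. The range was 0.73 to 0.76 between sessions 1 and 3, 0.84 to 0.85 between sessions 1 and 2 and 0.91 to 0.93 between sessions 2 and 3. The reference on the array of male 8 (session 2) thus lay nearer to session 3 than to session 1. If labelling or hybridisation acted on both dyes, the Cy3 shift between sessions 3 and 1 would be matched by the Cy5 shift of the females, and these correlated at 0.5381 over 2603 probes, between the bounds set for either outcome. At siah1 the Cy3 shift was 3.51 and the Cy5 shift 0.08, at ddit4 3.40 and 0.04 and at slc25a36a 3.77 and 0.18, while at ppiaa both were negative, at -2.78 and -3.92. A different batch of reference RNA may be part of the cause, sessions and females cannot be told apart in the Cy5 shift, and no biological explanation was tested.

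Riox2, cops6, ano10b and zgc:123258 varied together among the siblings. They were at 3.28 to 4.06 in female 4 and 4.14 to 5.26 in male 9, at -0.04 to 0.29 in female 8 and at 0.58 to 0.76 in male 8. A hypothesis of 1 inherited segment carrying these named genes needs them on 1 chromosome. The most on any chromosome was 1 (chromosomes 10, 14, 25 and 18), which argues against a segment carrying them. Probes of hdac1 (3.37 in female 4, -0.03 in female 8) and prpsap1 (2.31 and 0.11) had a similar profile. The other probes of riox2 lay between -0.89 and 0.30 in all 7 fish, and the other probe of zgc:123258 at 0.94 in female 4 and 0.01 in female 8. A sequence shared by these probes may be the source, and probe sequences were not analysed here. In that case the positions of the named genes do not give its place. The chromosomes thus cannot decide on a segment that holds such a sequence.

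If inherited segments or copy number shifted neighbouring genes together, differences between sisters scanned together might correlate between adjacent genes. Over 1305 pairs of neighbours the mean correlation across pairs was 0.0454 (0.037 for females 4 and 8, 0.053 for females 7 and 9). The prediction was a value above all 1000 shuffles of gene order, and the highest shuffle was 0.056, so it was not met. Shuffles at least as large as the observed value numbered 9 of 1000.

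Other splits of the fish into groups of the same sizes were fitted as well. Over all 7 fish the real split called 0 probes, a count that 35 of 35 splits reach of necessity, so the splits decide nothing there. The highest other split called 89. That highest split set females 7 and 9 and males 8 and 9 against females 4 and 8 and male 5, the fish of session 3, and so follows the scan sessions. With the scan session as a block the real split called 0. For the gene lists the real split called 16, 10 of 35 splits called as many, and the highest other called 19. All of these 10 kept males 8 and 9 on one side, so they share the contrast of these fish. The splits therefore cannot decide on chance, which is not excluded. Without male 5, 1 of 15 splits, the real one, called as many as 5757 probes and the highest other called 0, but 15 splits are too few for a share under 0.05.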
